A study of Homo sapiens with 12 samples.

How the data were processed

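The libraries came from primary human pulmonary artery endothelial cells, the cells that line the artery from the heart to the lung. RNA was measured by sequencing of stranded total RNA libraries, which keep both messenger and long noncoding RNA. The labels give 4 groups of 3 libraries: normoxia with a negative control siRNA, and hypoxia with the negative control siRNA, a KMT2E-AS1 siRNA or a KMT2E siRNA. An siRNA is a short RNA duplex designed to lower a chosen transcript. Per the labels, cells had an 8 h siRNA incubation and hypoxia was 0.2% oxygen for 24 h. The labels do not say whether libraries of one group came from separate cultures or donors, so p-values measure only the spread between these samples, which may be technical.

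The deposited table holds raw counts, whole numbers of reads per gene that the authors did not normalize, for 57820 genes in 12 libraries. Per the submitters' processing notes the tools used were STAR, featureCounts and DESeq2, with the hg19 genome build. Their versions, the annotation release and the strand setting of the counting are not given in the sources used here. Without a stated strand setting, reads of KMT2E and of its antisense neighbour KMT2E-AS1 cannot be told apart with certainty. Reads shared between near-identical copies also leave the cytosolic ribosomal protein, histone and mtDNA-encoded genes uncertain.

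Gene symbols and coordinates were taken by Ensembl identifier from GENCODE release 44 placed on GRCh37, the nuclear coordinates of hg19. Of the identifiers, 55538 matched a symbol and 2282 did not. The unmatched identifiers took between 1.38% and 1.77% of the counts per library and kept their identifiers.

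Total counts per library ran from 12018353 to 61592192. A floor of 3 counts corresponded to between 0.0487 and 0.25 CPM (counts scaled to a common library size). These floors cover counting error only. The replicates of each group were compared before averaging: chi-square per degree of freedom between pairs ran from 2.19 to 7.31, so no pair agreed within sampling noise.

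The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 and limma 3.58.1 in R 4.3.3) with TMM scaling, the filterByExpr filter and a robust fit over all 4 groups, which share one estimate of the spread. It ran on 15967 genes. Adjusted p is by Benjamini-Hochberg with a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic. The 95% intervals of folds come from these standard errors and so from the spread between libraries. Levels are CPM on TMM-scaled library sizes, as mean ± SD of 3 libraries. The exceptions, as CPM on total counts, are the sums of leukocyte markers, the LAPTM5 and IFNB1 levels beside them, and the floors. The comparisons were hypoxia against normoxia with the negative control siRNA, each siRNA against the negative control under hypoxia, and the 2 siRNA groups against each other.

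The gene lists and the rule for named genes were fixed before the data were examined. There were 29 lists, of which 28 had enough tested genes. They were HIF-responsive genes, glycolysis, HIF pathway components, nuclear oxidative phosphorylation genes, mtDNA-encoded proteins, TCA cycle, vasoactive mediators, BMP and TGF-beta signalling, DNA replication, mitosis, and endothelial identity. Also fixed were arterial, Notch and tip-cell genes, mesenchymal transition, extracellular matrix, YAP/TAZ targets, inflammatory adhesion and cytokine genes, interferon-stimulated genes, unfolded protein and integrated stress response, p53 targets, and cholesterol synthesis and uptake. The rest were H3K4 methylation enzymes, KMT2E neighbours, long noncoding RNAs, replication-dependent histones, cytosolic ribosomal proteins, and markers of smooth muscle and fibroblasts, leukocytes, epithelium and lymphatic endothelium. UHRF1, PECAM1, GJA5 and CCL5 were list members with no matching row. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation as an alternative.

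Named genes followed a rule. In each comparison it takes KMT2E-AS1 and KMT2E, and the 8 highest and 8 lowest log2 fold changes among genes that passed, with at least 5 CPM in the higher group and no overlap between the libraries, leaving out clone-style, small RNA and pseudogene names. From each called list it takes up to 4 members with the smallest adjusted p in the list's direction and 2 against it. It adds up to 4 passing members each of the HIF component, vasoactive and KMT2E neighbour lists, and 6 genes called in the same direction in both siRNA comparisons and 6 that differ between them. HIF1A, EPAS1, VEGFA, EDN1 and NOS3 could be named anywhere. XIST and Y-linked genes were left out. IFNB1, LAPTM5 and CD68 fall outside the rule and were chosen after their values were seen. Some genes that the rule takes are not reported here.

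Correlations between comparisons that share libraries were set beside 10 simulations with unchanged groups. Alternatives were DESeq2 1.42.0, limma-voom, other scalings and filters, a stricter threshold, a 1.5-fold minimum change, the 2 groups alone, tests without mtDNA and rRNA genes, a replicate block, and each library left out. One alternative was chosen after seeing the data: the deepest library thinned to the mean depth of the other hypoxic controls.

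The 3' UTR scan asked whether genes with a given 7-base word in the annotated 3' UTR had other fold changes than genes without it. It used a linear model with log2 UTR length, GC content, the square of each and their product as covariates. It covered 10449 genes with at least 5 CPM in a group and a UTR of at least 50 bases. The fold changes were permuted 100 times. Fold changes were limited to 3 on the log2 scale either way. Genes without an annotated 3' UTR were not searched. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used, and figures were drawn with matplotlib 3.10.9.

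The fits were tested on simulated counts with 200 changed genes per comparison. For hypoxia against normoxia, over 15466 genes, 42 of 49 genes simulated at a 2-fold change were called, and for KMT2E siRNA, over 15415 genes, 40 of 50. In the simulated hypoxia comparison 10 unchanged genes were called, 6.58% of calls. A list raised 1.5-fold was called in each simulated comparison, with 0 other lists. A word planted with a log2 change of 0.3 among 10449 genes ranked 1.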

Results

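RNA was counted per gene in primary human pulmonary artery endothelial cells, in 12 libraries of 4 groups with 3 libraries each. One group was kept in normoxia with a negative control siRNA. The other groups were held at 0.2% oxygen for 24 h with the negative control siRNA, an siRNA against the long noncoding RNA KMT2E-AS1, or an siRNA against KMT2E, a chromatin regulator of the KMT2 family. Libraries held between 12018353 and 61592192 counts. The deepest was replicate 1 of the hypoxic negative control and the shallowest replicate 3 of the hypoxic KMT2E siRNA group, while the others held between 19700545 and 27216727. The first 3 principal components took 44.7%, 22.1% and 14.6% of the variance.

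The targeted genes were examined first. KMT2E (ENSG00000005483.15, GRCh37 chromosome 7, 104581390 to 104755466, plus strand, protein coding) stood at 208 ± 9.47 CPM (SD, n = 3) in the hypoxic negative control and at 59.6 ± 1.89 CPM in the KMT2E siRNA libraries. It fell by 1.80 ± 0.04 on the log2 scale (SE), to 28.7% of the control (edgeR quasi-likelihood adjusted p = 3.13e-24). KMT2E-AS1 (ENSG00000239569.2, chromosome 7, 104653724 to 104654768, minus strand, long noncoding RNA) lies within the span of KMT2E and was low throughout. Its level was 1.07 ± 0.184 CPM in normoxia, 1.48 ± 0.109 in the hypoxic negative control, 1.72 ± 0.174 in the libraries labelled KMT2E-AS1 siRNA and 0.93 ± 0.291 in the KMT2E siRNA libraries.

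KMT2E-AS1 was not lower in the libraries labelled KMT2E-AS1 siRNA than in the control. The log2 fold change was 0.19 ± 0.23 (edgeR quasi-likelihood adjusted p = 0.505), and the 95% confidence interval of the fold ran from 0.827 to 1.57. The label of that group is therefore not borne out by the targeted gene, and each direction below is drawn for the libraries so labelled. KMT2E was lower there by a small step, with a log2 fold change of -0.19 ± 0.04. In the KMT2E siRNA libraries KMT2E-AS1 had a log2 fold change of -0.69 ± 0.27 (edgeR quasi-likelihood adjusted p = 0.0267). That call was lost without replicate 1 of the hypoxic control (-0.62, adjusted p = 0.106 by edgeR), without replicate 1 (-0.45, 0.199) or replicate 3 (-0.69, 0.0527) of the KMT2E siRNA group, and in DESeq2 (-0.68, 0.0902).

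**Figure D1:**
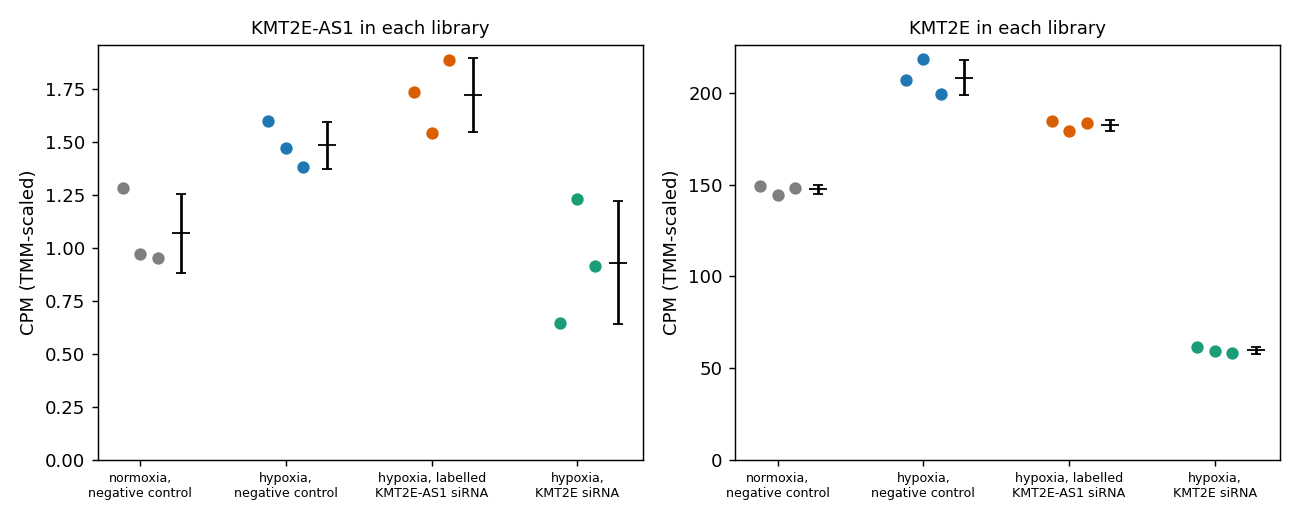
CPM of KMT2E-AS1 and KMT2E in each of the 12 libraries (points), with mean and SD of each group of 3 (bars). KMT2E averaged 59.6 CPM in the KMT2E siRNA group against 208 in its control, and KMT2E-AS1 averaged 1.72 CPM in the libraries labelled KMT2E-AS1 siRNA against 1.48.

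The comparison of hypoxia with normoxia, both with the negative control siRNA, asks what low oxygen changed in these cells. HIF-responsive genes rose and genes of cell division fell. VEGFA, which drives vessel growth, rose from 20 ± 1.63 to 256 ± 5.68 CPM (log2 fold change 3.67 ± 0.05), and the oxygen sensor EGLN3 rose by a log2 fold change of 6.34 ± 0.13. The glucose transporter SLC2A1 rose by 3.09 ± 0.06. The mitotic genes KIF20A and CDC20 fell by 3.29 and 3.53 on the log2 scale. The largest rise among named genes was in H19, an imprinted long noncoding RNA, from 7 counts over the normoxic libraries to 2936 (log2 fold change 8.22 ± 0.49).

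Of 37 tested HIF-responsive genes, 35 rose and 1 fell, with a median log2 fold change of 1.35. Their members include ANGPTL4 (3.65 ± 0.05) and ADM (2.03 ± 0.04), a vasodilator peptide, while HMOX1, heme oxygenase, fell by 1.44. In glycolysis 22 of 23 genes rose, among them LDHA (1.40 ± 0.04) and ALDOA (1.46 ± 0.04). Among 9 HIF pathway components 4 rose and 3 fell: EGLN1 rose by 1.55 ± 0.04 and HIF3A by 3.04 ± 0.10, while HIF1A and EPAS1, which encode the HIF alpha subunits, fell by 0.81 and 0.58. These 3 lists were called by camera and held with an estimated correlation, and the call of the HIF pathway components was lost without a low-count filter (camera adjusted p = 0.118).

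Cell cycle genes moved together. All 28 mitosis genes and all 31 DNA replication genes fell, with median log2 fold changes of -2.87 and -1.56; examples are CCNB1 (-2.90 ± 0.09), ASPM (-2.74 ± 0.07), MCM4 (-2.22 ± 0.07) and PCNA (-1.56 ± 0.06). Of 28 replication-dependent histone genes 25 fell, and 26 adjusted over the list alone, with H3C4 at -2.24 ± 0.09. Histone genes share sequence between copies, so single members are uncertain. These lists held with an estimated correlation. MCM10 fell by 4.03, and CYP1A1, an aryl hydrocarbon receptor target, fell by 3.94.

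Of 17 TCA cycle genes 14 fell, including OGDH (-0.68 ± 0.05) and FH (-0.61 ± 0.06), a call that held with an estimated correlation. Of 75 nuclear oxidative phosphorylation genes 46 fell and 4 rose (48 and 5 adjusted over the list alone), with ATP5MC1 at -1.02 ± 0.08, and of 13 mtDNA-encoded proteins 10 fell, with MT-CO1 at -0.73 ± 0.04. These calls were lost with adjusted p = 0.336 and 0.34 with an estimated correlation. Of 21 cholesterol synthesis and uptake genes 19 fell, including ACAT2 (-1.48 ± 0.09), with adjusted p = 0.0823 with an estimated correlation.

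Genes of vessel tone changed in both directions. EDN1, the vasoconstrictor endothelin-1, rose from 750 ± 17 to 1723 ± 28.5 CPM, and PTGIS, prostacyclin synthase, rose from 11 ± 2.54 to 351 ± 12.3 CPM. NOS3, endothelial nitric oxide synthase, fell by 1.08. Over the 16 tested vasoactive mediators 9 rose and 4 fell, with adjusted p = 0.0606 with an estimated correlation. Of 23 BMP and TGF-beta signalling genes 10 rose and 4 fell, among them ENG (1.11 ± 0.04), SMAD7 (2.22 ± 0.08) and ID1 (-0.66 ± 0.06), with adjusted p = 0.097 with an estimated correlation. Of 20 YAP/TAZ targets 12 rose and none fell, with CCN1 at 1.25 ± 0.04, and of 21 p53 targets 13 fell and 3 rose, with CDKN1A, the p21 cell cycle inhibitor, at -0.63 ± 0.04. Both of these calls held.

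In the extracellular matrix list 20 of 36 genes rose and 7 fell, with COL4A1 at 0.87 ± 0.04 (adjusted p = 0.183 with an estimated correlation). In mesenchymal transition 7 of 15 rose and 1 fell, with TAGLN at 2.37 ± 0.05 (adjusted p = 0.0686 with an estimated correlation). Of 23 unfolded protein and integrated stress response genes 12 rose and 4 fell, with ASNS, asparagine synthetase, at 2.09 ± 0.09 and ATF4 at 1.08 ± 0.04 (adjusted p = 0.251 with an estimated correlation). Of 18 arterial, Notch and tip-cell genes 9 rose and 5 fell, with PDGFB at 1.12 ± 0.04 (adjusted p = 0.0563 with an estimated correlation, and camera adjusted p = 0.0574 without a low-count filter). Of 17 long noncoding RNAs 12 rose and 2 fell, with MIR210HG at 5.67 ± 0.17, a call that held. Of 76 cytosolic ribosomal protein genes 54 rose and 2 fell (58 and 2 adjusted over the list alone), with a median of 0.16 and adjusted p = 0.664 with an estimated correlation.

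Among markers of other cells, 4 of 6 tested epithelial markers rose, with KRT8 at 0.97 ± 0.07 (adjusted p = 0.0993 with an estimated correlation). The epithelial call was lost with a stricter low-count filter (camera adjusted p = 0.0528). Not called were markers of smooth muscle and fibroblasts (2 of 10 higher, 2 lower) and of lymphatic endothelium (2 of 5 higher, 1 lower), endothelial identity (8 of 20 higher, 7 lower) and inflammatory adhesion and cytokine genes (5 of 20 higher, 10 lower). The H3K4 methylation enzymes (6 of 24 higher, 9 lower; 7 and 9 adjusted over the list alone) and KMT2E neighbours (2 of 9 higher, 3 lower) were not called either. Interferon-stimulated genes were not called, with a median of 0.05, 5 of 28 higher and 3 lower (3 and 2 adjusted over the list alone). That list passed, with a median of 0.28 and a camera adjusted p of 0.0247, when the deepest hypoxic control library was left out. Only 1 of 15 leukocyte markers was abundant enough to test, LAPTM5, with a log2 fold change of 0.01.

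By edgeR's quasi-likelihood test 8545 of 15967 genes differed, 4380 higher and 4165 lower in hypoxia, and 1474 changed by more than 1.5-fold. Counts of members adjusted over the list alone were the same as over all genes in 24 of 29 lists. With total counts as the only scaling the median of all genes shifted by -0.135, so small changes are relative to the scaling.

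**Figure D2:**
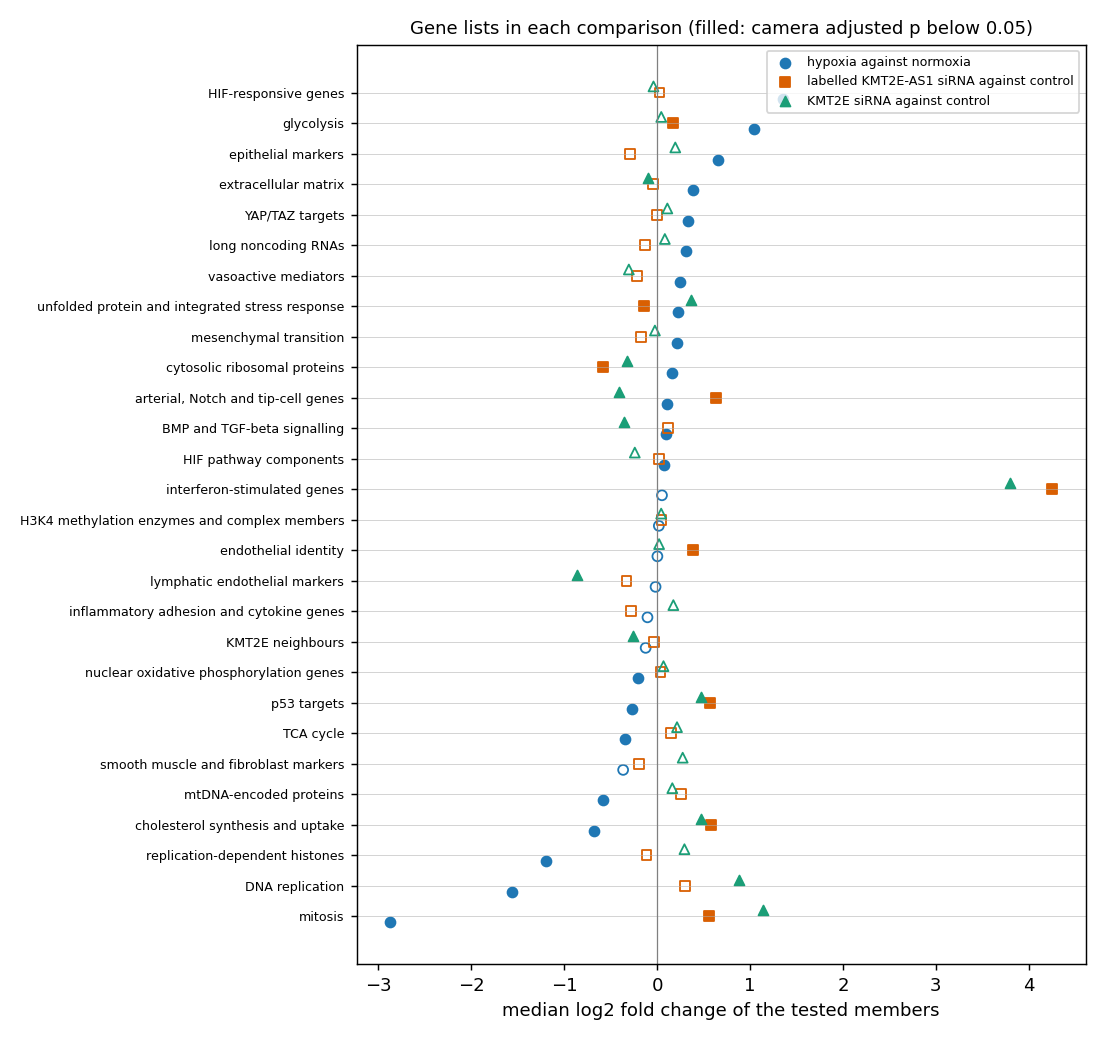
Median log2 fold change of the tested members of each of 28 gene lists in hypoxia against normoxia and in each siRNA group against the hypoxic negative control, with filled symbols for camera adjusted p below 0.05. Mitosis stood at -2.87 in hypoxia, and interferon-stimulated genes stood at 4.25 and 3.80 in the siRNA groups.

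The comparison of the libraries labelled KMT2E-AS1 siRNA with the hypoxic negative control asks what that siRNA changed under low oxygen. Interferon-stimulated genes rose. RSAD2, an antiviral enzyme, rose from 1.33 ± 1.03 to 467 ± 12.8 CPM (log2 fold change 8.81 ± 0.33), IFIT1 by 6.96 ± 0.37, MX2 by 7.32 ± 0.37 and CXCL10 by 6.97 ± 0.29, from 8 counts over the control libraries to 676. B2M, the light chain of class I antigen presentation, rose from 771 ± 52.3 to 3002 ± 75.3 CPM. VCAN, a matrix proteoglycan, and CXCL12, a chemokine, both fell by 3.59. VCAN is the 1 gene with the 7-base word ATACGGA in its 3' UTR among the 33 that the naming rule takes as lower here. Of all 10449 searched genes 212 carry it. VCAN fell further with KMT2E siRNA, where the 3' UTR scan gave this word a t of only -0.543. In the libraries labelled KMT2E-AS1 siRNA the word had a t of -5.57. A fall under another siRNA cannot decide whether the word has a part in the fall of VCAN here.

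Of 28 interferon-stimulated genes 27 rose and none fell, with a median log2 fold change of 4.25. The camera call was lost, with adjusted p = 0.0845 with an estimated correlation. LAPTM5, the only leukocyte marker abundant enough to test, rose in the same libraries by 0.63. Of 21 p53 targets 17 rose and 2 fell, including FAS, a death receptor (2.29 ± 0.11), MDM2 (0.77 ± 0.04) and CDKN1A (0.79 ± 0.04), and the call held. Of 18 arterial, Notch and tip-cell genes 13 rose and 2 fell (13 and 3 adjusted over the list alone), including NRP1 (0.98 ± 0.04), ANGPT2 (1.32 ± 0.05) and UNC5B (2.70 ± 0.15), and that call held as well. Endothelial identity genes rose in 14 of 20 and fell in 3 (14 and 4 adjusted over the list alone), with FLT1, a VEGF receptor, at 1.30 ± 0.04 and CDH5, VE-cadherin, at 0.58 ± 0.04 (adjusted p = 0.124 with an estimated correlation).

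Cholesterol synthesis and uptake genes rose in 17 of 21 (18 adjusted over the list alone), with HMGCS1 at 1.63 ± 0.06 and IDI1 at 1.38 ± 0.08 (adjusted p = 0.163 with an estimated correlation). Mitosis genes rose in 23 of 28 (24 adjusted over the list alone), with CCNB1 at 0.70 ± 0.11 (adjusted p = 0.729 with an estimated correlation). Glycolysis genes rose in 14 of 23 and fell in 5, with SLC2A3 at 1.98 ± 0.05 (adjusted p = 0.555 with an estimated correlation). Of 76 cytosolic ribosomal protein genes 73 fell, with RPL3 at -1.17 ± 0.04 and RPS3A at -1.21 ± 0.04 (adjusted p = 0.159 with an estimated correlation).

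In the unfolded protein and integrated stress response list 11 of 23 fell and 5 rose (12 and 5 adjusted over the list alone). PHGDH, the first enzyme of serine synthesis, fell by 2.32, ASNS by 2.27 and ATF4 by 0.86, while VLDLR rose by 1.60 ± 0.04 (adjusted p = 0.555 with an estimated correlation). EDN1 fell by 0.95 and PTGIS by 2.70, and NOS3 rose by 0.37 ± 0.08. HIF1A and EPAS1 did not pass, with log2 fold changes of -0.02 and 0.02. RELN, a gene near KMT2E, fell by 2.11.

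By edgeR's quasi-likelihood test 8813 genes differed, 4534 higher and 4279 lower, and 1572 changed by more than 1.5-fold. Upper quartile scaling shifted the median of all genes by -0.101. Under it the glycolysis call was lost (camera adjusted p = 0.0562) and HIF1A, at -0.12, passed (edgeR adjusted p = 0.0142).

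The comparison of the KMT2E siRNA libraries with the hypoxic negative control asks what this siRNA changed under low oxygen. Interferon-stimulated genes rose here too, with RSAD2 at 8.07 ± 0.34, IFIT1 at 6.04 ± 0.37 and B2M at 1.68 ± 0.04. VCAN fell by 4.78, MGP, a calcification inhibitor, by 3.51 and FABP4, a fatty acid carrier, by 3.59. HIF1A fell by 0.67, and EPAS1 and NOS3 rose by 0.31 ± 0.04 and 0.87 ± 0.08. EDN1 fell by 0.58.

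Of 28 interferon-stimulated genes 28 rose, with a median of 3.80 (adjusted p = 0.139 with an estimated correlation), and LAPTM5 rose by 0.19. Of 21 p53 targets 17 rose and 1 fell, with MDM2 at 1.14 ± 0.04 and FAS at 2.79 ± 0.11 (adjusted p = 0.0798 with an estimated correlation). Cholesterol synthesis and uptake genes rose in 17 of 21, with HMGCS1 at 1.15 ± 0.07 and IDI1 at 1.11 ± 0.08 (adjusted p = 0.309 with an estimated correlation). DNA replication genes rose in 28 of 31 and fell in none (28 and 1 adjusted over the list alone), with MCM4 at 1.34 ± 0.08, and mitosis genes in 26 of 28, with HMMR at 2.25 ± 0.17, while CCNA2, cyclin A2, fell by 1.07 (adjusted p = 0.314 and 0.335 with an estimated correlation). Of 76 cytosolic ribosomal protein genes 64 fell and 1 rose (adjusted p = 0.368 with an estimated correlation).

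Arterial, Notch and tip-cell genes fell in 11 of 18 and rose in 4, with EFNB2, an arterial ephrin, at -2.32 ± 0.08, NOTCH4 at -0.60 ± 0.05 and NRP1 at 1.02 ± 0.04 (adjusted p = 0.112 with an estimated correlation). Extracellular matrix genes fell in 18 of 36 and rose in 8 (18 and 9 adjusted over the list alone), with COL4A1 at -1.07 ± 0.04 (adjusted p = 0.426 with an estimated correlation). Of 5 lymphatic endothelial markers 4 fell, with MMRN1 at -1.32 ± 0.06 and PROX1 at -0.86 ± 0.10 (adjusted p = 0.216 with an estimated correlation). Unfolded protein and integrated stress response genes rose in 18 of 23, with HSPA5, a chaperone of the endoplasmic reticulum, at 0.77 ± 0.05 (adjusted p = 0.309 with an estimated correlation). KMT2E neighbours fell in 6 of 9, with RELN at -1.76 ± 0.06 (adjusted p = 0.309 with an estimated correlation). BMP and TGF-beta signalling genes fell in 16 of 23 and rose in 5, with TGFBR2 at -0.62 ± 0.03 (adjusted p = 0.426 with an estimated correlation). The word GGTTTTA is in the 3' UTRs of 14 of the 42 searched genes that the naming rule takes as lower here. Among these are EFNB2, NOTCH4, COL4A1, PROX1, TGFBR2, CCNA2 and KMT2E, which as the siRNA's own target says nothing about other transcripts. Of all searched genes 20.9% carry GGTTTTA, which was picked from these same fold changes. Its presence in KMT2E tells little, since 9 of the 15 words with the lowest t in hypoxia also occur in KMT2E transcripts.

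By edgeR's quasi-likelihood test 9077 genes differed, 4710 higher and 4367 lower, and 2049 changed by more than 1.5-fold. The BMP and TGF-beta call ended without replicate 3 of the KMT2E siRNA group (camera adjusted p = 0.0524) and with the replicate number as a block (0.0511).

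**Figure D3:**
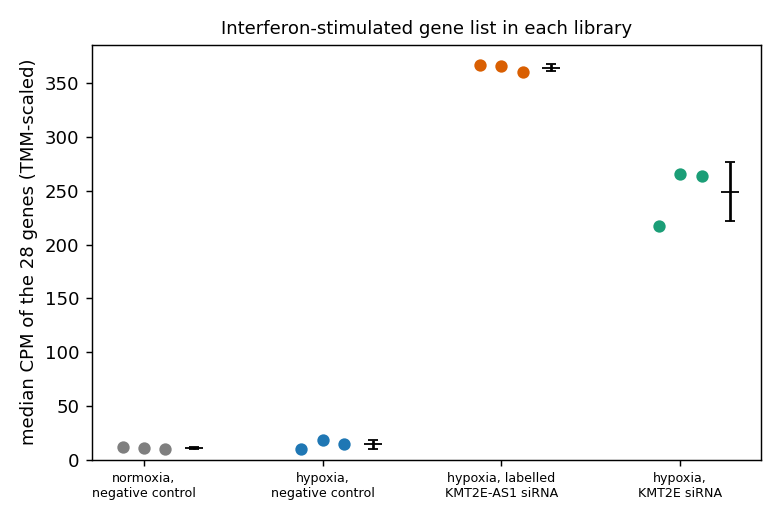
Median CPM of the 28 interferon-stimulated genes in each library (points), with mean and SD of each group of 3 (bars). The libraries labelled KMT2E-AS1 siRNA lay between 361 and 367 CPM and the KMT2E siRNA libraries between 218 and 266, while the negative control libraries lay between 9.67 and 18.4.

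The 2 siRNA groups were tested directly against each other, with positive values for higher levels in the libraries labelled KMT2E-AS1 siRNA. Arterial, Notch and tip-cell genes were higher there in 16 of 18 and lower in none, with PLVAP at 3.80 ± 0.12, EFNB2 at 2.18 ± 0.08 and DLL4, a Notch ligand, at 1.72 ± 0.07. Unfolded protein and integrated stress response genes were lower in 19 of 23, with PHGDH at -2.55 ± 0.09 and ASNS at -2.36 ± 0.10. Both list calls held with an estimated correlation. GJA1, the gap junction protein connexin 43, stood at 432 ± 7.57 against 74.8 ± 4.55 CPM (2.53 ± 0.04), and THBS1, thrombospondin 1, with ATACGGA in its 3' UTR, was lower (-1.57 ± 0.04).

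DNA replication genes were lower in 25 of 31 and mitosis genes in 23 of 28, with MCM10 at -2.01 ± 0.21 and UBE2C at -1.44 ± 0.15 (adjusted p = 0.278 and 0.581 with an estimated correlation). Endothelial identity genes were higher in 11 of 20, with FLT1 at 1.35 ± 0.04 and KDR at 0.66 ± 0.04 (adjusted p = 0.105 with an estimated correlation). HIF-responsive genes were lower in 19 of 37 and higher in 12, with LOX at -1.04 ± 0.04 and VEGFA at -0.44 ± 0.04 (adjusted p = 0.105 with an estimated correlation). BMP and TGF-beta signalling genes were higher in 12 of 23 (14 adjusted over the list alone; adjusted p = 0.278 with an estimated correlation). Cytosolic ribosomal protein genes were lower in 60 of 76 (61 adjusted over the list alone; adjusted p = 0.581 with an estimated correlation). Interferon-stimulated genes were higher in 13 of 28 and lower in 1 (14 and 1 adjusted over the list alone), with a median of 0.41 and a camera adjusted p of 0.0892. That list was called without replicate 2 of the KMT2E siRNA group (0.44, camera adjusted p = 0.0334), under upper quartile scaling (0.0353), with the replicate number as a block (0.0413), with the deepest library thinned (0.0473) and without a low-count filter (0.000203). By edgeR's quasi-likelihood test 7080 genes differed, 3540 in each direction, and 852 by more than 1.5-fold.

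The effects of the 2 siRNAs were correlated across genes, which are not independent replicates. Pearson's r was 0.721 over 15967 genes, against 0.403 in simulations of unchanged groups with the same shared controls, and the covariance was 0.356 against 0.0177. Both siRNA groups had 3037 genes higher and 2632 lower, where independent lists would give 1337.5 and 1170.3. TRIM22, PLSCR1 and SAMD9, interferon-induced genes, rose in both. The control group has 3 libraries, too few to split with at least 2 on each side, so part of the excess over independent lists may come from the shared controls.

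The siRNA effects were also set against the hypoxia effect, where the shared control enters with opposite signs. The correlations were -0.283 for the libraries labelled KMT2E-AS1 siRNA and -0.280 for KMT2E siRNA, against -0.439 and -0.419 in simulations, with covariances of -0.130 and -0.137 against -0.0175 and -0.0176. Of 4380 genes higher in hypoxia 2041 and 2036 were lower in these groups, where independent lists would give 1173.8 and 1197.9. Of 4165 genes lower in hypoxia 2097 and 2197 were higher, where independent lists would give 1182.7 and 1228.6. Independent lists leave out the shared control. In the simulations of unchanged groups, which keep it, a mean of 0.2 and 0.1 genes was called in both comparisons. Over all genes, called or not, the 2 effects had the same sign in 36.0% and 36.9%, against 34.3% and 35.0% in the simulations. Since the simulations hold no changed genes, these shares cannot say how much of the opposite movement comes from the shared control. PTGIS and EDN1 are examples that moved against their hypoxia change in the libraries labelled KMT2E-AS1 siRNA. The HIF-responsive list did not move that way as a whole and was not called by camera in either siRNA comparison. Of its 37 tested genes 16 were higher and 18 lower in the libraries labelled KMT2E-AS1 siRNA (median 0.03). With KMT2E siRNA 15 were higher and 14 lower (16 and 17 adjusted over the list alone, median -0.04).

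**Figure D4:**
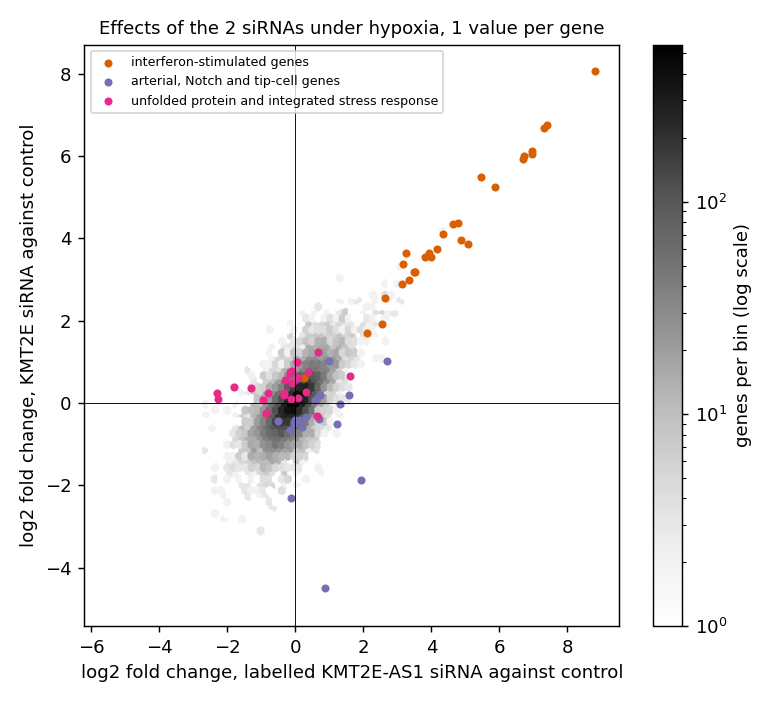
Log2 fold change of each of 15967 genes in the libraries labelled KMT2E-AS1 siRNA (x axis) and in the KMT2E siRNA libraries (y axis), each against the hypoxic negative control, with gray for the number of genes and color for 3 lists. Interferon-stimulated genes lie high on both axes, and r over all genes is 0.721.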

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

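The results here were chosen by a rule of opposite directions applied after the lists had been tested. Arterial, Notch and tip-cell genes moved in opposite directions under the 2 siRNAs. They were higher in the libraries labelled KMT2E-AS1 siRNA and lower with KMT2E siRNA, and the median difference between the groups was 0.73 on the log2 scale, tested directly by camera. The call of the fall with KMT2E siRNA was lost, with adjusted p = 0.112 with an estimated correlation. PLVAP stood at 34.8 and 2.45 CPM, against 9.03 in the hypoxic control, while NRP1 and UNC5B rose under both siRNAs.

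Unfolded protein and integrated stress response genes went the other way, with a median difference of -0.62, also called in the direct test. The calls against the control were lost, with adjusted p = 0.555 and 0.309 with an estimated correlation. PHGDH and HERPUD1 fell in the libraries labelled KMT2E-AS1 siRNA and rose with KMT2E siRNA. Over all genes, 730 were called in opposite directions in the 2 siRNA comparisons and differed between them, 460 higher in the libraries labelled KMT2E-AS1 siRNA and lower with KMT2E siRNA, and 270 the reverse. Opposite calls were fewer than independent lists would give, 1240.1 and 1262.2.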

How the results depend on the processing

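The alternative chosen after seeing the data was the thinned deepest library. Directions of the targeted genes did not turn under any setting. List medians close to 0 and counts close to an even split depend on the scaling. With total counts only, the median of all genes in hypoxia shifted by -0.135. HIF1A and EPAS1 in the libraries labelled KMT2E-AS1 siRNA, neither of which passed in the main test, changed sign. HIF1A stood at 0.00 with total counts only (0.001544), at 0.003677 in DESeq2 and at 0.016 without replicate 1 of the hypoxic control. EPAS1 stood at -0.08206 with upper quartile scaling and at -0.01248 without replicate 3 of the hypoxic control. With each library left out HIF1A ran from -0.04056 to 0.016 and EPAS1 from -0.01248 to 0.06723. Upper quartile scaling, total counts and DESeq2 moved the median of all genes in this comparison by about as much (-0.101, 0.0181 and 0.0201); for the left-out libraries the cause was not tested. Of the values of single genes and lists, 63 lost and 48 gained a call under the other settings, and 30 and 4 with one library left out.

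Counts of genes fell to 1474, 1572, 2049 and 852 (hypoxia, KMT2E-AS1 siRNA label, KMT2E siRNA, between siRNAs) when a change beyond 1.5-fold was required, which the setting itself asks for. Lists called fell to 10, 2, 0 and 2 with an estimated correlation, and with fry, which asks another question, stood at 21, 23 and 21 in the last 3. The correlation of the siRNA effects was 0.5072 with no low-count filter, 0.735 with at least 1 CPM in 3 libraries, 0.6338 by Spearman and 0.7794 at a mean CPM of 10 or more. The correlations with hypoxia were -0.3874 and -0.3501 with no filter, -0.3556 and -0.3289 by Spearman, and -0.2408 and -0.2284 at a mean CPM of 10 or more. The cause was not tested. KMT2E-AS1 under KMT2E siRNA was -0.6835 in DESeq2 and no longer passed.

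With each library left out, that value ran from -0.9963 to -0.4478, the correlation of the siRNA effects from 0.6923 to 0.7262, and those with hypoxia from -0.3043 to -0.2567 and from -0.2865 to -0.2349. Leaving out one library moved no count by over 1.5 times. The replicate numbers did not pair the samples: same-number deviations correlated from -0.0791 to 0.0955. With the replicate number as a block the counts were 8556, 8826, 9042 and 7100. Depth limits the values of KMT2E-AS1, which rest on 11 to 94 counts per library.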

Other observations

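Inflammatory and lymphatic genes also differed between the siRNA groups. In the inflammatory adhesion and cytokine list 15 of 20 genes were lower in the libraries labelled KMT2E-AS1 siRNA than with KMT2E siRNA and 2 were higher, with the chemokines CXCL1 at -2.51 ± 0.12 and CXCL2 at -1.23 ± 0.08, and IL6 at -1.08 ± 0.11 (adjusted p = 0.105 with an estimated correlation). Of 5 lymphatic endothelial markers 4 were higher, with FLT4, a VEGF receptor gene, at 248 ± 9.71 against 108 ± 5.27 CPM (adjusted p = 0.156 with an estimated correlation). Of 17 long noncoding RNAs 10 were lower and 2 higher (11 and 3 adjusted over the list alone), with HIF1A-AS3 at -1.65 ± 0.13 and MALAT1 at 0.31 ± 0.04 (adjusted p = 0.212 with an estimated correlation). Replication-dependent histones were lower in 16 of 28 (adjusted p = 0.581 with an estimated correlation).

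The tests on the interferon list and on KMT2E-AS1 were chosen only after the results were seen, and the lowest-t tests of the 3' UTR scan and the tests of other splits before. The first pattern is the rise of interferon-stimulated genes in both siRNA groups. Blood cells in the cultures are argued against: leukocyte markers other than LAPTM5 summed to at most 1.48 CPM in any library. The sum tried first, without CD68, missed its bound of 5 CPM and reached 136 CPM, but it rests on LAPTM5, which the normoxic and hypoxic negative control libraries also hold at 93.1 and 85.8 CPM; the sum rose from 86.6 CPM in the hypoxic control to 135 and 101 in the siRNA groups. Loss of KMT2E mRNA stays open in the libraries labelled KMT2E-AS1 siRNA, which hold at least 179 CPM of KMT2E with the list at 361 CPM or more. The normoxic control holds less KMT2E, 147 ± 2.65 CPM, with the list at most at 11.9, but it also differs in oxygen. Against the hypoxic control KMT2E was lower in these libraries (log2 fold change -0.19 ± 0.04), so a level from normoxia cannot decide. Sensing of the siRNA duplexes stays open in both groups. In the KMT2E siRNA libraries it and loss of KMT2E mRNA cannot be told apart. The list's median was 0.41 higher where KMT2E was higher, with a fry adjusted p of 0.055 and a camera call under some settings. IFNB1 summed to 37 counts in both siRNA groups, 15 with the KMT2E-AS1 siRNA label and 22 with KMT2E siRNA, against 3 in the hypoxic control. The mean levels were 0.219, 0.390 and 0.0433 CPM. The control cells got an siRNA duplex too, and there were neither untransfected cells nor a second siRNA per target.

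The second pattern is KMT2E-AS1, which was not lower in the libraries labelled KMT2E-AS1 siRNA. Too few counts to see a large loss are argued against, since the lower bound of the 95% interval of the fold was 0.827. Reads of KMT2E counted as KMT2E-AS1 stay open: KMT2E-AS1 had a log2 fold change of -0.69 in the KMT2E siRNA libraries, between no change and the -1.80 of KMT2E. An siRNA directed outside the annotated gene may be another reason. The joined word ATACGGAA, from the scan below, is in 0 of 4 annotated KMT2E-AS1 transcripts but occurs on its strand at 104652273 and 104655813 of chromosome 7 (GRCh37), 1444 bases downstream and 1045 bases upstream, where 2.64% of 1439 windows at other gene starts hold it and 1 holds it at 2 sites. The gene with its flanks on this strand and the annotated transcripts of both genes were searched, and the opposite strand was not. A search of several places leaves this open.

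The third pattern is in the 3' UTRs. siRNAs can lower transcripts that match their first bases, the seed, and such matches are a candidate explanation for part of the lower genes. In the KMT2E siRNA libraries the lowest t over 16190 words was -11.8, for GGTTTTA, against -5.40 in permutations and -4.86 in the hypoxia comparison. The adjusted difference was small, -0.19 on the log2 scale over 2187 genes. Of genes with the word 43.9% were called lower against 27.6% without. Such shares of called genes are not adjusted for UTR length or GC content. In the libraries labelled KMT2E-AS1 siRNA the lowest t was -5.57, for ATACGGA, against -5.09 in permutations, but the word is not in an annotated KMT2E-AS1 transcript, so the source stays open. ATTAACT was higher in both siRNA groups (t 7.24 and 6.92) and not in hypoxia (0.17), which may reflect a seed of the shared negative control, a test chosen after the scan.

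Between the siRNA groups GGTTTTA had the highest t, 14.8, against 4.95 in permutations, but the word was picked from the same KMT2E siRNA libraries. Of genes with it 43.4% were called higher in the libraries labelled KMT2E-AS1 siRNA, against 25.8% without. Of genes named above as higher there, EFNB2, FLT1 and KDR carry it, while PLVAP, DLL4, GJA1 and FLT4 do not. Of the 8 highest genes 3 carry it (MFSD14B, DPY19L1 and ACER2), as do 2 of the 7 searched among the 8 lowest. The share over all searched genes was 20.9%. Of the searched genes that the naming rule takes with KMT2E siRNA, 14 of 42 called lower carry GGTTTTA, the target KMT2E included. Of those called higher 5 of 52 do. For ATACGGA in the libraries labelled KMT2E-AS1 siRNA it is 1 of 33 and 0 of 49, and 212 of all 10449 searched genes.

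The 6 libraries of each comparison can be split in 10 ways, the real one included, too few for a share under 0.05. In each comparison 1 split, the real one, gave as many calls, with 8545 genes for hypoxia, 8813 and 9077 for the siRNAs and 7080 between them, and at most 0 in any other split by edgeR's quasi-likelihood test. At an unadjusted p under 0.05 the highest other splits had 596, 382, 634 and 648 genes. Every other split mixes libraries of the 2 groups, which widens the spread on each side. With so many genes differing, few calls were bound to follow there, so the 0 is no test of the real split.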
